A study of Mus musculus with 8 samples.

How the data were processed

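Polyadenylated RNA from 4 mouse pancreatic cancer cell lines, each with a WT and a C1galt1c1-KO culture, was sequenced as paired ends after capture on oligo(dT) beads, per the labels' protocols. The protocols name a NovaSeq instrument and the series' design text a HiSeq, a difference left open here. Spike-in RNA was added per the labels' protocols and was not used here. The deposited values are TPM, transcript shares scaled by gene length, in 1 table of 49315 gene identifiers and 8 libraries. Per the submitters' processing notes the tools were cutadapt 5.1, STAR 2.7.11b, featureCounts 2.1.1 and DESeq2 2.11.40.8, with the mm39 build. How TPM were made from the reads, with which gene lengths and annotation, is not given in the sources used here.

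Each library sums to 1000000 TPM, so the values are shares and keep no depth. Gene names and positions were taken from GENCODE vM39 on GRCm39, the same assembly as mm39, which matched 45505 identifiers and left 3810 without a name. Depth was estimated from the smallest steps between low TPM values and the exon lengths of that annotation, a step tested on simulated data. The simulation used the same lengths, so it cannot show how far other lengths would change the estimate. The estimate was 62830372 and 46335347 assigned reads for the WT and KO libraries of 6694c2, 59771516 and 61392619 for 2838c3, 59067887 and 41034399 for 6499c4 and 46818963 and 47998369 for 6419c5. Between 59.0% and 61.8% of low values came out within 0.1 of a whole read, since the lengths used by the authors may differ. These estimates lie above the depth in read pairs that the design text states, and it is not settled whether both mates of a pair were counted. With them, 1 read in a gene of 2000 bases is worth 0.038 to 0.055 TPM.

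Genes with a TPM of at least 1 in at least 4 of the 8 libraries were kept, 12900 in all, 136 of them without a name. limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with genotype and cell line as terms and a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on this log2(TPM + 1) scale, which understates the change of low genes. The cell line is a block because WT and KO libraries of a line come from the same line. Same-line libraries deviated together from their group means, with r of 0.66, 0.42, 0.79 and 0.75 in 6694c2, 2838c3, 6499c4 and 6419c5. The labels do not say that the WT and KO cultures of a line were repeated, so limma p-values of single genes measure the spread between the 4 lines.

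Each KO library correlated best with its own parent, with r from 0.934 to 0.982, against at most 0.925 with another parent. Both 0.934 and 0.925 belong to the 2838c3 KO library, the latter with the 6694c2 parent. Xist was listed between 3.93 and 32.0 TPM in 3 lines and at or below 0.0839 TPM in 6499c4, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at or below 0.234 TPM in all libraries.

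Gene lists, the design and most other settings tried were fixed before the data were examined. Of 40 lists, 35 had at least 5 genes tested and entered camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. The 5 others were not tested: MHC class II (1 gene, highest member Lgmn at 155 TPM), fibroblast markers (1 gene, Gsn at 330 TPM), immune markers (2 genes, Cd68 at 28.1 TPM), endothelial markers (2 genes, Egfl7 at 14.8 TPM) and acinar and islet markers (3 genes, Cela1 at 44.4 TPM), each with its highest level in any library. The named genes are the 10 with the largest change in each direction among genes past the threshold that moved the same way in all 4 lines, filled up with those of smallest unadjusted p and a log2 change of at least 0.5, predicted genes skipped. Beside them stand C1galt1c1, C1galt1, the 4 members of smallest p in the direction of each list that passed, and 1 member of each other list. 1 gene that the rule names is not reported here.

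The limma step was tested on simulated data for the KO against WT comparison with 12900 genes and independent noise: 62% of 100 genes with a log2 change of 1 and 100% of 100 genes with a log2 change of 2 were recovered, with 13 false calls. Alternatives were another pseudocount (0.1), other filters (none, or a TPM of 5), median-ratio scaling, quantile normalization, no variance trend, robust variance, no line block, and each line left out in turn. A count test had been planned where whole reads could be recovered. It was not run, because they could not, and limma-voom on estimated reads was used in its place. That alternative, the removal of structural RNA and the removal of lines 6694c2 and 6419c5 were chosen after seeing the data. Structural RNA here means identifiers without a name and the small RNA classes of the annotation. The annotation gives no class for the unnamed identifiers, so counting them as structural is an assumption. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.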

Results

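RNA sequencing of polyadenylated transcripts was carried out on 4 mouse pancreatic ductal adenocarcinoma cell lines, 6694c2, 2838c3, 6499c4 and 6419c5. Each line was sequenced once as its wild-type (WT) parent and once after knockout (KO) of C1galt1c1, which gives 8 libraries, 4 per genotype. C1galt1c1, also called Cosmc, encodes a chaperone that the core 1 O-glycan synthase C1galt1 needs to fold, and cells without it carry the truncated Tn O-glycan. The comparison of KO with WT asks which transcripts differ when C1galt1c1 is knocked out. No glycan is measured in these data, so the loss of core 1 O-glycans rests on the labels. Expression was given as TPM, length-scaled transcript shares that add up to 1000000 in each library. The reads assigned to genes, estimated from the smallest TPM steps, ranged from 41034399 to 62830372 per library. Each line has 1 library per genotype, so a difference within a line has no replicate check. The limma tests of single genes rest on the spread of the KO effect between the 4 lines.

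C1galt1c1 mRNA fell in the KO libraries of all 4 lines. Its level went from 37.0 to 10.9 TPM in 6694c2, from 40.4 to 15.3 TPM in 2838c3, from 54.2 to 19.0 TPM in 6499c4 and from 37.9 to 16.1 TPM in 6419c5. The KO libraries held 36.2% ± 5.38 (SD, n = 4 lines) of the parental level. The gene (ENSMUSG00000048970) lies on the minus strand of chromosome X at 37719034 to 37724025 in GRCm39, and its coding sequence, 37720047 to 37720994, sits within a single exon. The limma estimate was a log2 change of -1.42 with an SE of 0.15 and a 95% interval of -1.76 to -1.07, or -1.27 relative to all genes. Its unadjusted limma p of 3.21e-05 was the smallest of the 12900 genes tested. As a single test planned for this gene it passed, while its Benjamini-Hochberg adjusted limma p over all genes was 0.278. The exact two-sided paired sign-flip test gave p = 0.125, the smallest that 16 sign patterns allow. C1galt1 itself (ENSMUSG00000042460, chromosome 6, 7844634 to 7875687) stood at 69.3%, 180%, 65.5% and 98.9% of the parental level in 6694c2, 2838c3, 6499c4 and 6419c5. Its limma estimate was a log2 change of -0.07 with an SE of 0.25, or 0.07 relative to all genes. Either value was smaller than the spread between lines.

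**Figure D1:**
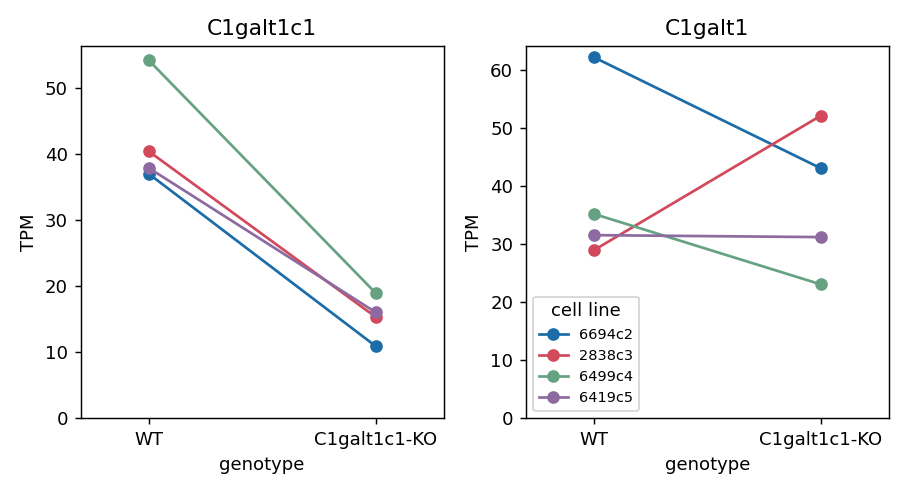
TPM of C1galt1c1 (left) and C1galt1 (right) in the WT and KO library of each cell line, each line joining the 2 libraries of 1 cell line. C1galt1c1 lies between 37.0 and 54.2 TPM in the WT libraries and between 10.9 and 19.0 TPM in the KO libraries, while C1galt1 goes in different directions.

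The libraries differed in structural RNA. Identifiers without a name in the annotation held 12.5% of the TPM in the 6694c2 KO library and 9.69% in the 6419c5 KO library, against 1.22% and 1.05% in their parents. In 2838c3 they held 0.713% in the WT and 1.21% in the KO library, and in 6499c4 1.11% and 1.33%. The RNA class of these identifiers is not known here. The small RNA classes of the annotation held 1.10% and 0.879% of the 6694c2 and 6419c5 KO libraries, against 0.162% and 0.204% in their parents. The identifier ENSMUSG00000076258 alone held 8.83% of the 6694c2 KO library and 6.50% of the 6419c5 KO library. Rmrp, the RNA of the RNase MRP complex, was 47.2-fold and 192-fold higher in the same 2 KO libraries, and Rpph1, the RNA of RNase P, 25.3-fold and 76.9-fold. The 6419c5 folds are uncertain in size, because its WT library held only 1.90 TPM of Rmrp and 1.6 TPM of Rpph1, against 365 and 124 TPM in its KO library. Because TPM are shares of a library, such RNA lowers the share left to other genes. The median log2 change of all genes was -0.15, and changes below are given relative to this median unless stated otherwise. The limma tests of single genes, those adjusted over a list alone included, use the values before this shift is taken off. The list test fry uses them too and sets a list against no change, while camera sets a list against the other genes.

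**Figure D2:**
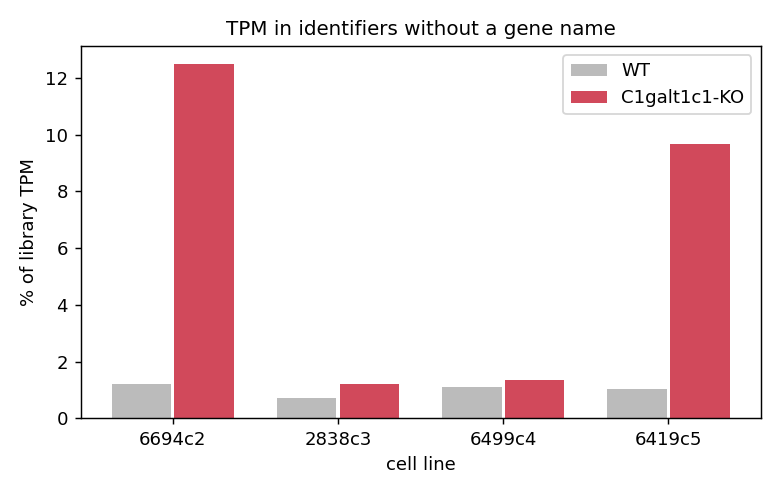
Percent of the library TPM (vertical axis, from 0) in identifiers without a gene name, for the WT (grey) and KO (red) library of each cell line, 1 library per bar. The KO libraries of 6694c2 and 6419c5 reach 12.5% and 9.69%, and the other 6 libraries lie at or below 1.33%.

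Among the genes with the smallest unadjusted p that moved the same way in all 4 lines, the higher ones in KO included Ptgs2, the inducible cyclooxygenase, at 58.5 ± 32.0 TPM against 20.5 ± 9.35 TPM in WT (SD, n = 4 libraries), a log2 difference of 1.48 with an SE of 0.20. Gadd45a, a stress-inducible growth-arrest gene, stood at 1.37 (SE 0.22), the EGF receptor ligand Areg at 1.41 (SE 0.28), the collagenase Mmp13 at 1.23 (SE 0.19) and the stress transcription factor Ddit3 at 1.61 (SE 0.32). Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, stood at 1.21 (SE 0.18). Arid5a, Rhox5 and Hapln4 had differences of 0.98, 0.79 and 1.18. Prl2c3 stood at 2.19, but it belongs to a family of near-identical genes whose reads can be shared, and its value is uncertain. The lower ones besides C1galt1c1 included Tfrc, the transferrin receptor, at 64.1 ± 22.1 TPM against 145 ± 30.5 TPM (SD, n = 4 libraries), a log2 difference of -1.05 with an SE of 0.16. Atp9a, a P4-type ATPase, stood at -1.42 (SE 0.20), the protease gene Bace2 at -1.35 (SE 0.20) and Ambp, the precursor of alpha-1-microglobulin, at -1.28 (SE 0.17). Atoh8, the R-spondin receptor Lgr4, the sodium pump subunit Atp1b1, the serine protease Tmprss2 and the sulfate transporter Slc26a2 had differences of -0.99, -0.95, -0.90, -0.89 and -0.71.

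None of these genes passed: 0 of 12900 genes had a Benjamini-Hochberg adjusted p under 0.05 with limma-trend. At an unadjusted p under 0.05 there were 1137 genes, 111 higher and 1026 lower, so 90.2% were lower. After scaling each library by its median ratio there were 292 higher and 347 lower (54.3% lower), again with 0 genes past the adjusted threshold. limma-voom on estimated reads also gave 0 genes, with 289 higher and 379 lower at an unadjusted p under 0.05.

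**Figure D3:**
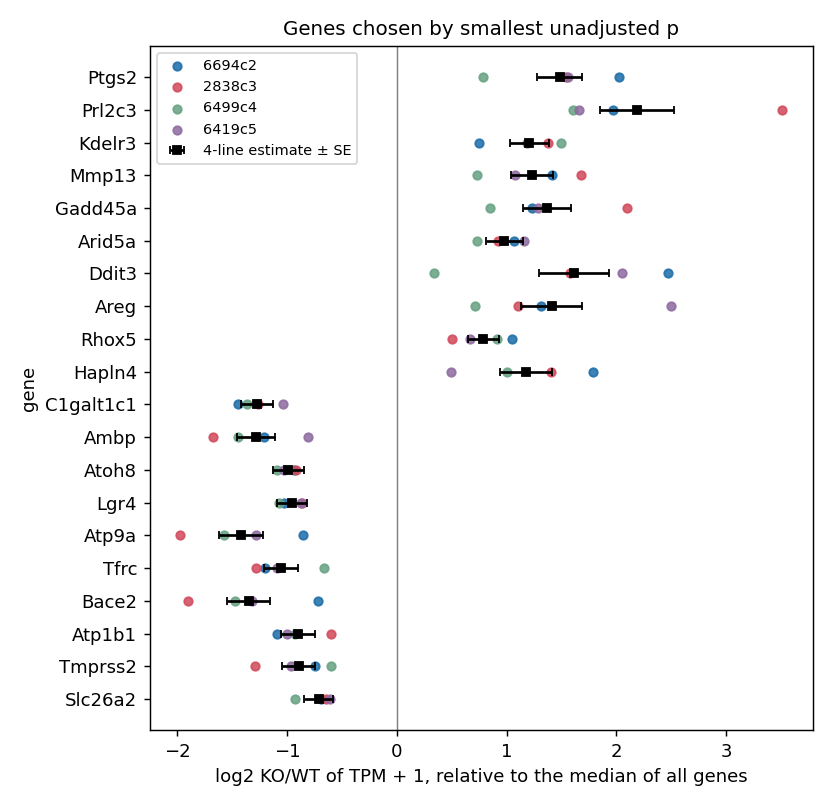
Log2 KO/WT of TPM + 1 for the 20 genes chosen by smallest unadjusted p and the same direction in all 4 lines. Coloured points are the 4 cell lines, each relative to that line's own median of all genes, and squares with bars are the limma estimate ± SE relative to the median of all genes, from 2.19 for Prl2c3 to -1.42 for Atp9a.

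The KO minus WT differences were unlike between the lines. With 1 library per genotype in each line, a line-specific KO effect cannot be told apart from differences between cultures or libraries. The number of genes at least 2-fold higher or lower relative to the median was 360 and 409 in 6694c2, 760 and 834 in 2838c3, 145 and 162 in 6499c4 and 269 and 186 in 6419c5. Across the 12900 genes, which are not independent replicates, Pearson's r between the KO effects of 2 lines averaged 0.045 over the 6 pairs of lines. It was highest for 6694c2 with 6419c5, at 0.37, and lowest for 2838c3 with 6419c5, at -0.20. The share of genes that moved in 1 direction in all 4 lines was 13.2%, where independent directions give 12.5%. By comparison, 2178 genes differed between the lines at an adjusted limma p under 0.05 (F-test on the line terms). This count fell to 745 without line 6419c5 and 758 without 6499c4, rose to 3785 without 2838c3, and was 1077 without both lines whose KO libraries held the structural RNA.

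Of 35 gene lists that could be tested, 12 passed the camera test with its preset correlation, 9 higher and 3 lower in KO. The preset of 0.01 treats the genes of a list as nearly independent, so these p-values do not measure the spread between lines. The estimated correlation was 0.54 for the integrated stress response and 0.87 for G1/S, but -0.02 for complement. With an estimated correlation 0 lists passed, and fry, which asks whether the genes of a list move 1 way on balance, also gave 0 after adjustment. Without line 2838c3 the camera count was 22. Without both 6694c2 and 6419c5 it was 10, of which 4 were among the 12: G1/S, ribosomal proteins, mesenchymal, and hypoxia and glycolysis. Leaving out a single line ended 8 of the 12 calls. Without 6694c2 the adjusted camera p was 0.19 for Golgi, 0.98 for the unfolded protein response and 0.13 for chemokines, and without 6499c4 it was 0.12 for mesenchymal and 0.093 for hypoxia and glycolysis. Without 6419c5 it was 0.092 for RAS-MAPK output, 0.060 for complement and 0.22 for epithelial genes. Without the line block it was 0.34 for complement and 0.38 for epithelial genes, and both median-ratio scaling and voom ended the chemokine call (0.11 with each). Quantile normalization ended 3 calls, with 0.054 for ribosomal proteins, 0.21 for hypoxia and glycolysis and 0.11 for chemokines. With no filter on low values it was 0.45 for both chemokines and complement and 0.082 for hypoxia and glycolysis, with a TPM minimum of 5 it was 0.055 for both epithelial genes and chemokines, and with a pseudocount of 0.1 it was 0.064 for complement. Other settings brought calls. Median-ratio scaling, quantile normalization, voom and the removal of structural RNA each brought the same 3, G2/M, cholesterol biosynthesis and the classical subtype, all lower. With no filter oxidative phosphorylation (lower, 0.021) came beside them, and without the line block G2/M and cholesterol biosynthesis did. Within single lists, adjusted over the list alone, 19 list entries in 9 lists passed, 6 higher and 13 lower, against 0 adjusted over all genes. Cfb is among them under both NF-kB targets and complement. This adjustment does not cover the number of lists looked at, so how many entries would pass by chance is not known. These calls depend on the scaling, as 14 of the 19 passed with median-ratio scaling, 15 with structural RNA left out, 12 with voom and 9 with quantile normalization, and on the line block, as 0 passed without it. With a line left out between 4 and 15 of them passed, and Ptgs2 was the 1 gene that passed without each line in turn. Without both 6694c2 and 6419c5 2 of the 19 passed, and with no filter on low values 10 did.

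The integrated stress response list, genes driven by ATF4 during amino acid shortage or endoplasmic reticulum stress, was higher in KO, with a relative median of 0.63 over 26 genes (camera adjusted p = 1.74e-19, adjusted p = 0.56 with an estimated correlation). The difference lay in 2 lines: the relative median was 1.63 in 6694c2 and 1.33 in 6419c5, but -0.26 in 2838c3 and 0.06 in 6499c4. The KO libraries of 6694c2 and 6419c5 are the ones with 12.5% and 9.69% of their TPM in unnamed identifiers, and without these lines the list had an adjusted p of 0.97 and the opposite direction. Adjusted over the list alone 2 genes passed and rose, Ddit3 and Nupr1, each higher in all 4 lines. Their adjusted limma p was close to the threshold, at 0.0496 each. Both failed with a pseudocount of 0.1 (0.052), a TPM minimum of 5 (0.051), no filter (0.10) and no variance trend (0.072). Both passed with median-ratio scaling (0.027) and quantile normalization (0.025), and each passed in 2 of the 4 line omissions. Trib3 was at 2.53 in 6694c2 and 3.21 in 6419c5, against 0.23 and 0.53 in 2838c3 and 6499c4, and Sesn2 had an overall difference of 0.92. The unfolded protein response list followed the same lines, with medians of 0.81, -0.26, -0.06 and 0.31 in 6694c2, 2838c3, 6499c4 and 6419c5 (camera adjusted p = 8.4e-05, adjusted p = 0.67 with an estimated correlation), and 0 of its 27 genes passed adjusted over the list alone. Without 6694c2 and 6419c5 its direction turned (adjusted p = 0.059). Hyou1, a chaperone of the endoplasmic reticulum, was at 1.82 in 6694c2 and -0.26 in 2838c3, and Edem1, Ern1 and Derl1 had overall differences of 0.37, 0.41 and 0.31.

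Cell cycle genes differed most between the 2 libraries of 2838c3, whose WT library had the highest level of 34 of 35 G2/M genes and 31 of 32 G1/S genes among the 8 libraries. Its KO library had the lowest level of 21 G2/M and 18 G1/S genes. The G1/S list was lower in KO overall (relative median -0.59, 32 genes, camera adjusted p = 3.93e-08, adjusted p = 0.67 with an estimated correlation), with medians of -0.54, -1.83, -0.25 and 0.24 in 6694c2, 2838c3, 6499c4 and 6419c5, and 0 genes passed adjusted over the list alone. Chaf1b, Rrm1, Dtl and Ccne2 had differences of -0.84, -0.57, -0.75 and -0.88. The G2/M list (35 genes) did not pass (camera adjusted p = 0.0617, adjusted p = 0.89 with an estimated correlation), with medians of -2.90 in 2838c3 and 1.03 in 6419c5, and its gene with the smallest p was Hjurp at -0.22. It passed as lower with median-ratio scaling (0.00052), voom (4.7e-05), structural RNA left out (0.0075) and no line block (0.00013), and as higher without 2838c3 (0.00036). Hypoxia and glycolysis genes went the other way in the same line, at 1.65 in 2838c3 and 0.51 in 6499c4, but -0.92 in 6694c2 and -0.44 in 6419c5. That list passed as higher (36 genes, camera adjusted p = 0.000903, adjusted p = 0.89 with an estimated correlation), although its median change was -0.03 and its mean 0.02 before the shift of all genes was taken off, and without line 2838c3 it passed as lower (adjusted p = 0.035). Vegfa, Hk2, Ero1a and Ndrg1 were at 2.25, 0.87, 3.39 and 1.80 in 2838c3. Replication-dependent histones did not pass (adjusted p = 0.193, H2bc8 at -0.45).

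Epithelial genes were lower in KO (26 genes, relative median -0.18, camera adjusted p = 0.0239, adjusted p = 0.60 with an estimated correlation). Of these genes 15 lay below and 11 above the median of all genes, with 8 lower and 2 higher in all 4 lines. Adjusted over the list alone 7 genes passed, all lower in each of the 4 lines: the tight junction genes Ocln, Cldn7, Marveld3 and Tjp3, the cadherin Cdh3, the desmosome gene Dsp and the transcription factor Elf3. With median-ratio scaling 3 of the 7 passed, Ocln, Cldn7 and Cdh3. With quantile normalization the smallest limma p among them, adjusted over the list alone, was 0.058, for Ocln and Cldn7. Ocln, Cldn7, Cdh3 and Marveld3 passed in 2 of the 4 line omissions, Elf3 and Tjp3 in 1 and Dsp in 0. Tjp3, Dsp and Elf3 lie outside the rule for named genes and were chosen after their values were seen. Ocln went from 29.4 ± 5.57 to 13.6 ± 4.88 TPM (SD, n = 4 libraries), a log2 difference of -0.96 with an SE of 0.19. The mesenchymal list was higher (19 genes, relative median 0.21, camera adjusted p = 0.00081, adjusted p = 0.56 with an estimated correlation), with medians of -0.28, 0.43, 0.45 and 0.25 in 6694c2, 2838c3, 6499c4 and 6419c5. None of its genes passed adjusted over the list alone (0 of 19). Snai2 had a difference of 1.21, Inhba 1.04 and Acta2 0.64, each carried in part by 1 line: Snai2 was at 2.54 in 6694c2 and 0.78 overall without it, Inhba at 2.28 in 2838c3 and 0.63 without it, and Acta2 at 1.60 in 6419c5 and 0.31 without it. Inhba was at -0.23 in 6694c2 and Acta2 at -0.08 in 2838c3. The classical subtype list did not pass (adjusted p = 0.0617, adjusted p = 0.56 with an estimated correlation, Vsig1 at -0.60) but passed as lower with median-ratio scaling (0.021), voom (0.011) and structural RNA left out (0.031). The basal-like list did not pass (adjusted p = 0.0617); in it Areg passed adjusted over the list alone.

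**Figure D4:**
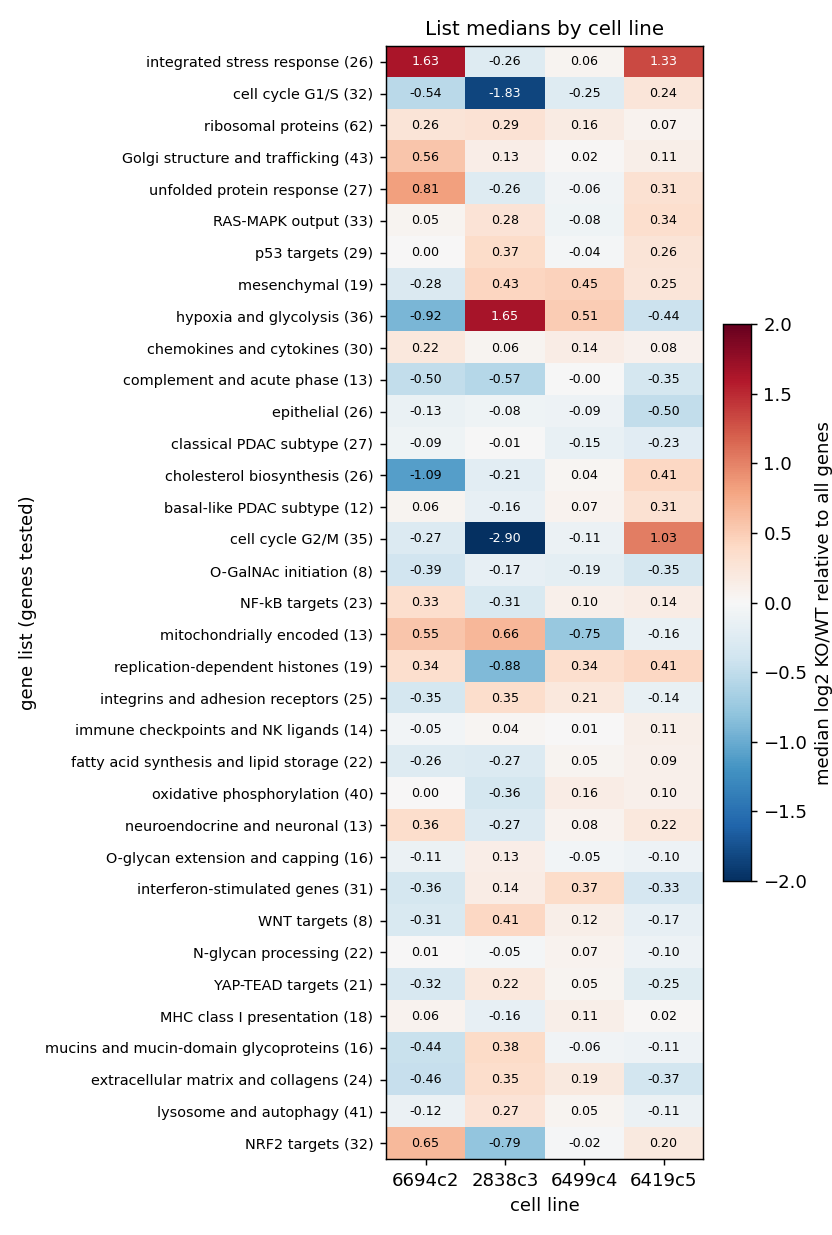
Median log2 KO/WT of each gene list (rows, with the number of genes tested) in each cell line (columns), relative to that line's median of all genes, in red where higher and blue where lower in KO. The integrated stress response list stands at 1.63 and 1.33 in 6694c2 and 6419c5, and the G2/M list at -2.90 in 2838c3 and 1.03 in 6419c5.

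Complement and acute phase genes were lower (13 genes, relative median -0.33, camera adjusted p = 0.0163, adjusted p = 0.56 with an estimated correlation). Cfb, complement factor B, was lower in all 4 lines, at -0.71 with an SE of 0.16, and passed adjusted over the list alone. Cfi, C1ra and Hp had differences of -0.95, -0.43 and -1.09, but Cfi was at 0.23 in 2838c3 and Hp at 0.38 in 6499c4. Hp was also low, at 0.67 ± 0.60 TPM in KO against 5.13 ± 5.95 TPM in WT (SD, n = 4 libraries). Chemokines and cytokines were called higher (30 genes, camera adjusted p = 0.00653, adjusted p = 0.56 with an estimated correlation), with 0 genes past the threshold adjusted over the list alone. The direction was the opposite with fry, whose reference is no change. That reference alone does not give the turn, since the list's median before the shift was 0.052 and its mean 0.0013. Of the 30 genes 18 lay above and 12 below the median of all genes, with 6 higher and 3 lower in all 4 lines. Before the shift 1 gene was higher and 4 were lower at an unadjusted limma p under 0.05. Il34, Il1rn, Csf2 and Vegfa, named by the rule from the higher genes only, had differences of 1.03, 0.51, 0.55 and 0.80. The NF-kB target list did not pass (adjusted p = 0.131), but adjusted over the list alone Ptgs2 rose and Cfb fell. Interferon-stimulated genes (adjusted p = 0.544, Ifit2 at -0.69), MHC class I genes (adjusted p = 0.77, H2-Q4 at -0.47) and immune checkpoints with NK ligands (adjusted p = 0.267, Raet1e at 0.74) did not pass.

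The glycosylation lists did not pass camera, or fry for a move 1 way. The fry test for changes in either direction, unadjusted, gave its smallest p for O-glycan extension and capping (7.8e-05) and O-GalNAc initiation (8.9e-05). Epithelial genes came next (0.0020), while N-glycan processing (0.17) and mucins (0.45) stood apart. This test uses values before the shift, so the shift of all genes also enters it. For O-GalNAc initiation, the step before core 1 synthesis, camera gave an adjusted p of 0.0923 over 8 genes (0.035 without 2838c3, lower). Adjusted over the list alone 3 of these transferases fell, Galnt4 at -0.46, Galnt11 at -0.47 and Galnt7 at -0.39, the last at 0.04 in 6694c2. With median-ratio scaling Galnt4 and Galnt11 passed over the list alone (adjusted p = 0.046 each) and Galnt7 did not (0.10), and with quantile normalization 0 of the 3 did. Galnt11 and Galnt7 were chosen after their values were seen. In O-glycan extension and capping (adjusted p = 0.419, 16 genes) the fucosyltransferase Fut4 fell adjusted over the list alone, at -0.95 with an SE of 0.19 and lower in all 4 lines. N-glycan processing (adjusted p = 0.691, Man1a2 at -0.33) and mucins (adjusted p = 0.788, Muc1 at -0.43) did not pass. The Golgi structure and trafficking list was higher (43 genes, relative median 0.23, camera adjusted p = 1.72e-05, adjusted p = 0.56 with an estimated correlation), with medians of 0.56 in 6694c2, the line with the most structural RNA in its KO library, and 0.02 in 6499c4. Kdelr3 rose adjusted over the list alone. Sec24d, Golga5 and Golga4 had differences of 0.45, 0.42 and 0.40.

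Ribosomal protein genes were higher (62 genes, relative median 0.20, or 0.055 before the shift, camera adjusted p = 3.93e-08, adjusted p = 0.56 with an estimated correlation), with Rpl26, Rpl37, Rps19 and Rpl34 at 0.37, 0.33, 0.27 and 0.27 and 0 genes past the threshold adjusted over the list alone. The p53 target list was higher (29 genes, camera adjusted p = 0.000558, adjusted p = 0.56 with an estimated correlation), although its median before the shift was -0.01 and its mean 0.06. Cdkn1a, an inhibitor of cyclin-dependent kinases, was at 2.32, 1.63 and 1.57 in 2838c3, 6499c4 and 6419c5 but 0.11 in 6694c2. Gdf15 and Bbc3 had differences of 1.36 and 0.54. Gdf15 and Sesn2 belong to both this list and the integrated stress response list, so the 2 calls are not separate. Gdf15 was at 1.76 in 6694c2 and 3.16 in 6419c5, against -0.28 in 2838c3 and 0.79 in 6499c4. The RAS-MAPK output list was higher (33 genes, relative median 0.19, camera adjusted p = 0.000242, adjusted p = 0.56 with an estimated correlation), with Dusp5, Ier3 and Egr3 at 0.87, 0.73 and 0.55. In both lists 0 genes passed adjusted over the list alone.

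The other lists did not pass. Their adjusted camera p was 0.0617 for cholesterol biosynthesis (Hsd17b7 at -0.47), 0.296 for fatty acid synthesis (Acsl3 at -0.37), 0.296 for oxidative phosphorylation (Sdha at -0.21) and 0.192 for mitochondrially encoded genes (mt-Nd3 at -0.20). It was 0.247 for integrins (Itgb6 at -0.62), 0.894 for extracellular matrix (Lamb2 at -0.45), 0.669 for WNT targets (Ccnd1 at -0.21) and 0.694 for YAP-TEAD targets, where Gadd45a rose adjusted over the list alone. It was 0.96 for NRF2 targets (Hmox1 at 1.27), 0.903 for lysosome and autophagy (Gusb at -0.35) and 0.296 for neuroendocrine genes (Scg5 at -0.31). Cholesterol biosynthesis genes had a median of -1.09 in 6694c2 and 0.41 in 6419c5, and the list passed as lower with median-ratio scaling (0.014), voom (0.010), structural RNA left out (0.020) and no line block (0.0047), with an adjusted p of 0.89 with an estimated correlation.

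Single lines decided several of these values. Without 2838c3 camera also passed NF-kB targets (0.00099), histones (2.0e-06), neuroendocrine genes (0.0042), NRF2 targets (0.00079), the basal-like list (0.026) and the classical subtype (0.025, lower), and mucins and extracellular matrix (0.020 each, lower). Without 6694c2 it passed integrins (0.021), interferon-stimulated genes (0.035), and as lower NRF2 targets (0.012), the classical subtype (0.023) and G2/M (0.023). Without 6499c4 it passed mitochondrially encoded genes (0.00020), and as lower oxidative phosphorylation (0.038), cholesterol biosynthesis (0.031) and G2/M (0.034), and without 6419c5 cholesterol biosynthesis (1.2e-06) and G2/M (5.5e-11), both lower. Of the 83 genes named by the fixed rule, 33 moved by over 1.5 times in the relative difference when 1 line was left out, and 2, C1galt1 and Ero1a, turned. Without 6694c2 Hyou1 was at 0.11, Itgb6 at -0.30, Hsd17b7 at -0.21, mt-Nd3 at -0.05, Bbc3 at 0.32, Sec24d at 0.29 and Golga5 at 0.21. Without 2838c3 Ero1a was at -0.09, Ndrg1 at 0.06, Vegfa at 0.32, Hk2 at 0.17, Ifit2 at -0.31, C1ra at -0.29, Ier3 at 0.46, Golga4 at 0.24, Sdha at -0.13, Ccnd1 at -0.04 and Gusb at -0.18, and the cell cycle genes Chaf1b, Rrm1, Dtl, Ccne2 and Hjurp at -0.48, -0.36, -0.43, -0.52 and -0.10. Without 6419c5 Gdf15 was at 0.75, Dusp5 at 0.44, Csf2 at 0.35, Muc1 at -0.29 and H2-Q4 at -0.31, and without 6499c4 Scg5 was at -0.13.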

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

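The tests of the 3 patterns weighed here were chosen after the results were seen, and what the counts of other splits would show was also written down only after those counts were known.

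In the KO libraries of 6694c2 and 6419c5, and not in the others, 12.5% and 9.69% of the TPM lay in identifiers without a gene name, which no gene list or named gene covers although 136 of them are among the genes tested, where the highest WT library had 1.22%. The same 2 libraries had high integrated stress response genes. Structural RNA displacing other transcripts is argued against as the cause of the list change, because it can only lower the shares of other genes, and before any correction the lower of the 2 list medians was 1.17. A knockout effect shared by the 4 lines cannot be told apart from chance differences between cultures, since with 1 library pair per line the upper 95% bound of the mean list median is 2.16 and the lower bound is -0.79. Culture conditions, RNA quality or poly(A) capture of these 2 libraries may also account for it and stay open: the lines share changes outside the list (r = 0.32 across protein-coding genes), and histone genes, whose mRNAs mostly lack poly(A) tails, had medians of 0.34 and 0.41 there but also 0.34 in 6499c4.

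Cell cycle genes were lower in the 2838c3 KO library than in its parent, with a G2/M change of -2.90 against 1.03 in 6419c5 (untested), and the WT library contributes, as it had the highest level of 34 of the 35 genes. A mislabelled library is argued against, because 79.3% of the 29 genes that mark the 2838c3 parent were highest in its own KO library, where C1galt1c1 was also low. The separation is narrow: that KO library had r of 0.934 with its own parent and 0.925 with the 6694c2 parent. It also had the highest KO level of 31.1% of the genes that mark the 6694c2 parent. A shared knockout effect cannot be told apart from culture differences, as the mean G2/M median over the 4 lines has a 95% interval from -3.21 to 2.08. A denser or less well supplied KO culture, or an unusual WT culture, may account for it: hypoxia and glycolysis genes changed by 1.65 in that line and by -0.92 in 6694c2 (untested), the design text states harvest at matched confluence, and no value here decides.

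More genes were lower than higher at an unadjusted p under 0.05. Structural RNA displacing other transcripts was not the whole cause, since 79.2% of such genes were still lower after it was left out, while the median of all genes moved from -0.15 to -0.07. Without both lines that hold it 65.1% were lower. With median-ratio scaling, quantile normalization and voom 54.3%, 50.8% and 56.7% were lower, so most of the excess goes with a shift of all genes together, which such scaling removes by construction. The origin of the rest of that shift stays open.

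The design allows 8 ways to swap genotypes within lines, too few for a share under 0.05. No gene passed the adjusted threshold in the real grouping or in any other (8 of 8 reach the real count of 0, highest other 0). For gene lists 6 of 8 reached the real count of 12, and the highest other was 18. For genes at an unadjusted p under 0.05 after median-ratio scaling 3 of 8 reached 639, with 1358 as the highest other. For genes moved by at least 0.5 in 1 direction in all 4 lines 2 of 8 reached 42, with 52 as the highest other. The grouping with 2838c3 and 6499c4 swapped gave the highest value in each of the last 3, which points to a structure of the samples: it sets 6694c2 and 6419c5 apart from the other lines, as the structural RNA does.

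Other lists moved in opposite directions in 2 lines, untested: mitochondrially encoded genes at 0.66 in 2838c3 and -0.75 in 6499c4, and NRF2 targets at 0.65 in 6694c2 and -0.79 in 2838c3. A single library stood apart from the other 3 of its genotype in 14 of 174 groups checked, where chance gives about 1 in 20, or 9. In WT these were Tfrc (99.6 TPM) and Ern1 (9.63 TPM) and Rpl34 (751 TPM) in 2838c3, Muc1 (145 TPM) in 6694c2, and Raet1e (3.78 TPM), Hsd17b7 (43.7 TPM) and Sec24d (21.8 TPM) in 6499c4. In KO they were Prl2c3 (3.55 TPM), Acta2 (33.2 TPM) and Scg5 (2.83 TPM) in 6419c5, Hyou1 (267 TPM) and Ier3 (375 TPM) in 6694c2, Raet1e (6.29 TPM) in 6499c4 and Rrm1 (20.5 TPM) in 2838c3.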

How the results depend on the processing

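The count of 0 genes at an adjusted limma p under 0.05 was 0 under all 15 alternatives, the fit without the line block (no replicate block) included, with smallest adjusted p from 0.221 to 0.9995. C1galt1c1 kept its direction and side of the threshold, from -1.49 to -1.33 as each line was left out and with no replicate block at -1.42. The block changed no call of C1galt1c1 and left the list count at 12, of which 10 were shared. The count of lists, 12, became 0 with an estimated correlation and 0 with fry, and ranged from 11 to 22 as each line was left out, 22 without 2838c3. The count of genes that differ between lines, 2178, ranged from 745 to 3785 as each line was left out and was 1077 without 6694c2 and 6419c5, where fewer samples were tested. For the named genes, 1122 of the alternative values kept their direction and 12 changed sign; no gene passes in any setting, so their side of the threshold could not change. For lists 138 kept both, 50 lost the call and 4 changed direction. Lists outside the 12 gained calls: 3 each with median-ratio scaling, quantile normalization, voom and structural RNA left out, 4 with no filter, 2 without the block, 6 without 6694c2 and 6419c5, and 2 to 10 as each line was left out. The 19 calls adjusted over a list alone became 0 without the block and 2 without 6694c2 and 6419c5. Before the shift of all genes is taken off, C1galt1 was -0.074 in the main fit. It was 0.080 with median-ratio scaling, 0.069 with quantile normalization and 0.0099 with structural RNA left out. It was 0.12 without 6694c2 and 6419c5 and 0.085 with voom, and ranged from -0.37 to 0.10 as each line was left out. Over the same omissions Hyou1 ranged from -0.014 to 0.63, Hk2 from -0.0074 to 0.27, Ero1a from -0.26 to 1.13, Ndrg1 from -0.11 to 0.66, and the adjusted p of the hypoxia and glycolysis list from 2.68e-10 to 0.0933, with the direction turned without 2838c3 (0.035). Without 6694c2 and 6419c5 Hyou1 was -0.21 and the adjusted p was 0.059 for the unfolded protein response list and 0.97 for the integrated stress response list, both turned. The chemokine list turned with fry (adjusted p = 0.83), although its median change before the shift was 0.052. The cause of the turns was not tested. The alternatives without 2 lines, without structural RNA and with voom were chosen after seeing the data. The planned count test was not run, because whole reads could not be recovered. Depth is known only as an estimate, and at 0.038 to 0.055 TPM per read in a 2000-base gene it limits genes near 1 TPM most.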

Other observations

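The values in this part were chosen after they were seen. No KO against WT difference in this part is past the adjusted limma threshold. Among the 42 genes that moved by at least 0.5 in 1 direction in all 4 lines, 18 higher and 24 lower, 7 of the higher and 3 of the lower were structural or unnamed RNA. The others included Hmox1, heme oxygenase, at 1.27 relative to all genes, and the cytokine Il34 at 1.03. Tfrc, which brings iron into cells, was lower at -1.05. Icosl, a ligand of the T cell receptor Icos, was at -0.70, Sult1a1, a sulfotransferase, at -1.04 and Ugt2a3, a glucuronosyltransferase, at -1.12. Of the other splits of the samples the highest gave 52 such genes.

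The lines differed in Cdkn2a, a tumour suppressor gene often lost in pancreatic cancer (limma F-test on the line terms, adjusted p = 6.6e-05). It was at 5.76 and 5.21 TPM in the WT and KO libraries of 6694c2, against 520 and 536 TPM in 2838c3, 1237 and 1507 TPM in 6499c4 and 1212 and 1088 TPM in 6419c5.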
